A study of Arabidopsis thaliana with 6 samples.

How the data were processed

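RNA was sequenced from root segments of Arabidopsis thaliana, a small plant used as a laboratory model, in 2 genotypes: the wild type Col and a line labelled myb68 myb84. Per the labels, plants grew on plates under continuous light at 22 °C, the uppermost 2 cm of the primary root was taken at 18 days, and each of the 3 biological replicates per genotype pooled at least 40 plants. Groups and replicate numbers were taken from the sample titles and genotype labels.

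The deposited files hold 1 column of raw counts per library, whole numbers of reads or fragments assigned to each of 32833 gene identifiers, with no normalization. Per the submitters' processing notes, the tools named were Trim Galore, HISAT, featureCounts and DESeq2, and the genome build was TAIR10. Their versions, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical gene copies, therefore cannot be told apart with certainty. Overlapping genes are marked where they are named, while near-identical copies were not searched for and are marked only in some cases.

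Gene symbols, products and positions came from the TAIR10.1 reference annotation, in which 32536 identifiers had an entry and 297 had none, 285 of the latter being organelle genes. Total counts ran from 19446419 to 55907128 per library. A count of 0 allows up to 3 counts, which is 0.154 CPM (counts per 1e6 library counts) in the shallowest library and 0.0537 CPM in the deepest. Intervals on counts were exact Poisson intervals at a confidence level of 95%, and they cover counting error only.

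The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with robust dispersion estimates, TMM scaling, the filterByExpr filter at its minimum count of 10 and Benjamini-Hochberg adjustment, with genotype as the only term. Genes with an adjusted p under 0.05 were called changed. Log2 fold changes are myb68 myb84 over wild type, and the standard error is the fold change divided by the square root of F. Levels are CPM after TMM scaling, as mean ± SD over 3 libraries. The p-values measure the spread between replicate pools of plants.

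The 25 gene lists, with 426 members, and the rule for genes to be named were fixed before the data were examined. Of the members, 396 were tested. Each list was counted gene by gene, over all genes and adjusted over the list alone, and tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 25 lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry, a rotation test of whether a list moves in one direction by itself, were alternatives.

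The genes to be named are the 6 members of the MYB68 subclade, the 10 largest changes in each direction among called genes with a mean CPM of at least 2 and no overlap between the groups, up to 6 called members of each list with the smallest adjusted p (or the 2 most abundant members of a list without calls), any member of the suberin, suberin transcription factor, cambium and cell cycle lists, and the 3 most abundant called genes in each direction. Genes outside this rule are said to have been chosen after their values were seen.

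The alternatives were DESeq2 size factors in the same fit, upper-quartile scaling, no low-count filter, a stricter filter (CPM of at least 1 in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, removal of organelle genes, GC content and length offsets (loess span 0.5, available for 99.4% of tested genes), each library left out in turn, stricter thresholds, and a prior count of 0.5 for the lists. After seeing the data, thinning of every library to 19446419 counts and the lists under other scalings were added.

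The edgeR step was tested on simulated counts for the 20941 tested genes. The genes to change were drawn from those outside the lists with a mean CPM of at least 2. Recovery at lower levels was not tested. The step recovered 72 of 100 genes changed 1.5-fold and 92 of 100 changed 2-fold, and 16 of its 199 calls were unchanged genes (8.04%). With no gene changed it made 0 calls and called 0 lists. The simulated genes were drawn independently of one another. False list calls under correlation between genes, estimated at 0.52 for the suberin list in the real counts, were thus not checked. A simulated list shift of -0.50 on the log2 scale was returned as a median of -0.50. On the same counts with changed genes, unchanged genes called numbered 25 in DESeq2 and 16 in limma-voom. They numbered 32 with the replicate block and 17 with GC and length offsets.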

Results

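Transcript levels were compared between the wild type Col and a line labelled myb68 myb84 in the uppermost 2 cm of 18-day-old primary roots, the oldest part of the root, where the cork layer (phellem) with its suberin forms in this species. MYB68 and MYB84 encode R2R3 MYB transcription factors of one subclade, and the comparison addresses how they affect suberin deposition and stem cell proliferation. There were 3 libraries per genotype, each from a pool of at least 40 plants. Total counts were 51770078, 26856622 and 19446419 in WT 1, 2 and 3, and 40401311, 32216039 and 55907128 in myb68 myb84 1, 2 and 3. Organelle genes held 0.294% to 0.340% of the counts and the 10 most abundant genes 4.53% to 5.54%.

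The genotypes separated on the first principal component, which held 44.5% of the variance, and the second (21.6%) held mainly a spread among the wild-type libraries, with WT 2 at 34.5 and WT 3 at -33.3. Spearman correlations were 0.990 to 0.996 between libraries of one genotype and 0.985 to 0.989 between genotypes. No pair of libraries was alike within sampling noise, since chi-square per degree of freedom was at least 10.7.

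Of the genes named in the genotype label, MYB84 transcripts were lower in the line labelled myb68 myb84 and MYB68 transcripts were not. The sample labels name myb84, while the series' design text has MYB86 in its place at 1 point, and the sources used here do not settle the difference. MYB84 (AT3G49690, chromosome 3, 18427735 to 18429281) had 9.92 ± 2.69 CPM in wild type and 6.0 ± 1.14 CPM in the mutant (n = 3 each), a log2 fold change of -0.70 with a standard error of 0.19 and an adjusted p of 0.0442. MYB68 (AT5G65790, chromosome 5, 26322817 to 26324609) had 53.7 ± 7.42 CPM in wild type and 67.8 ± 7.03 CPM in the mutant, a difference of 0.34 ± 0.10 (SE) that did not pass (adjusted p = 0.0613). The nature of the mutations is not given in the sources used here, so transcript counts of MYB68 do not check the label. Among their relatives, MYB36, a regulator of Casparian strip formation, rose by 0.52 (adjusted p = 0.00206) and MYB87 rose by 0.46 (adjusted p = 0.0443). MYB38 (0.16) and MYB37 (-0.15) did not pass (adjusted p = 0.315 and 0.526). The subclade thus had 2 members raised and 1 lowered of 6 (3 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.298). The MYB84 call ended when WT 1, WT 3, myb68 myb84 1 or myb68 myb84 2 was left out (adjusted p up to 0.149), with limma-voom (0.0552) and with GC and length offsets (0.0595), and the MYB87 call ended in each fit with a library left out but that without myb68 myb84 3 (up to 0.140), with upper-quartile scaling (0.0532) and with limma-voom (0.0635). MYB68 passed as higher without WT 3 (adjusted p = 0.00666), without myb68 myb84 1 (0.0471), in DESeq2 (0.0311), in limma-voom (0.0452) and with no low-count filter (0.0407).

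Across the transcriptome, 1739 of 20941 tested genes changed (8.30%), 975 of them higher and 764 lower in myb68 myb84. Most changes were small: the median size among called genes was 0.54 on the log2 scale, and 284 genes changed at least 2-fold, 151 raised and 133 lowered. The biological coefficient of variation was 10.3%. The groups did not overlap in 1731 of the called genes and in 27.2% of all tested genes, against 10% by chance. The number of called genes was 1024 without WT 1, 1062 without myb68 myb84 2 and 1068 without myb68 myb84 3.

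The largest rises included genes linked to light, the circadian clock and heat. ELIP1 (AT3G22840), an early light-induced chlorophyll-binding protein, went from 1.15 ± 0.38 to 8.02 ± 2.46 CPM, a log2 fold change of 2.82. PRR9 and CDF1, both clock-related transcriptional regulators, rose by 2.01 and 1.83, and MBF1C, a coactivator of the heat response, rose by 2.21. The copper amine oxidase gene AT2G42490 showed the most precise large rise, from 36.2 ± 2.59 to 209 ± 4.43 CPM (log2 2.53, SE 0.08, adjusted p = 3.01e-10). ADF9, an actin-depolymerizing factor, the chitinase gene AT2G43620, UGT84A2, a glucosyltransferase of phenolic acids, and the kinase gene AT3G61080 rose by 2.19, 1.98, 1.86 and 1.79. The uncharacterized gene AT1G75945 had 4 counts over the wild-type libraries and 1151 over the mutant libraries, with 8.80 ± 0.68 CPM in the mutant and a lower counting bound of 85.5 on the ratio. Each of these calls stayed in every fit with a library left out. MBF1C and AT3G61080 overlap annotated neighbours, and reads of the pairs cannot be told apart without strand.

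The largest falls included near-complete losses of transcript. Of the 8 genes lowered at least 16-fold, 5 were consecutive tested genes on chromosome 1, from AT1G09910 to AT1G09950 (3220035 to 3241863 in TAIR10.1). AT1G09920 had 4039 counts over the wild-type libraries and 2 over the mutant libraries, and AT1G09932 had 539 and 2, so the wild type was higher by a ratio of 2647 (95% counting interval 732 to 21861) and 353 (97.3 to 2924). HEMA2 (AT1G09940), a glutamyl-tRNA reductase of tetrapyrrole synthesis, went from 40.4 ± 3.55 to 0.0862 ± 0.0458 CPM, and AT1G09910, a rhamnogalacturonate lyase family gene, went from 36.4 ± 1.35 to 0.426 ± 0.0669 CPM. RAS1 (AT1G09950, named after its values were seen) had 158 counts in wild type and 0 in the mutant. This is 69.0-fold lower against a floor of 3 counts over the group, with a lower 95% counting bound of 55.5 on the ratio. The nearest tested genes on either side, AT1G09900 and SUT4, did not pass, at 109% and 102% of their wild-type levels. Elsewhere, AT1G27565 had 725 counts in wild type and 0 in the mutant (317-fold lower against the same floor). AT5G65400, AT4G02210, AT5G24240, DEL2, an atypical E2F factor, and the GDSL lipase gene AT1G28590 fell by 4.88, 4.79, 3.39, 2.68 and 2.29 on the log2 scale. AT4G02210 and AT5G24240 overlap annotated neighbours.

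**Figure D1:**
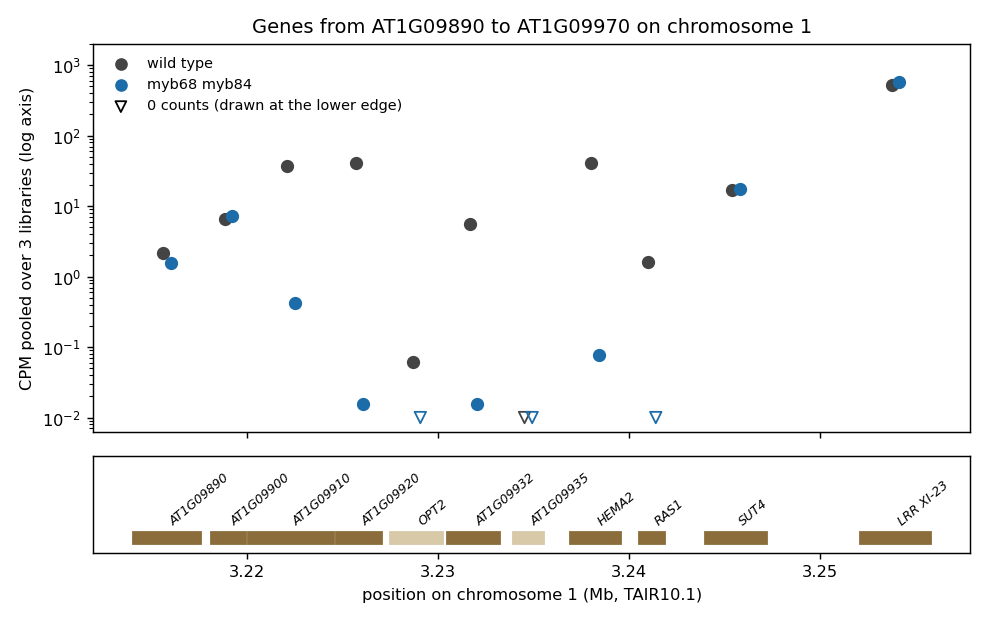
Transcript levels of genes along chromosome 1 (horizontal axis, Mb) as CPM pooled over 3 libraries (vertical axis, log scale), with wild type in grey, myb68 myb84 in blue and gene positions below (light boxes were too low to test). The 5 tested genes from AT1G09910 to AT1G09950 (RAS1) lie at 1.14% of the wild-type level or less in the mutant, and open triangles mark 0 counts.

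Among the most abundant changed transcripts, the aquaporins PIP2A and PIP1B rose by 0.56 and 0.60 and the chaperone gene HSC70-1 rose by 0.44. The papain family protease gene AT4G11320, the lipid transport family gene AT4G23670 and MLP34 fell by 0.68, 0.60 and 0.48 on the log2 scale. AT4G11320 went from 5430 ± 254 to 3378 ± 448 CPM. The HSC70-1 call ended without WT 1, WT 2 or myb68 myb84 1 (adjusted p up to 0.0855), and the MLP34 call ended when any 1 library but myb68 myb84 3 was left out (up to 0.0834).

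Genes of suberin biosynthesis and export were lower in myb68 myb84. Of 23 tested members, edgeR called 17 lowered and 0 raised and 6 did not pass, and adjusted over the list alone 19 fell and 0 rose. At an unadjusted p under 0.05, 19 were lower and 0 higher, DESeq2 called 18 lowered and 0 raised, and limma-voom called 17 and 0. The list median was -0.47 on the log2 scale, a level of 0.724 times wild type. Enzymes of chain elongation, hydroxylation, reduction and acyl transfer and wall and membrane proteins were among them. CYP86A1, the fatty acid omega-hydroxylase of root suberin, went from 223 ± 9.61 to 153 ± 13.7 CPM (log2 -0.55, SE 0.08, adjusted p = 0.00108). The elongase KCS20, the reductases FAR1, FAR4 and FAR5, which make suberin alcohols, and the acyltransferase GPAT5 fell by 0.58, 0.48, 0.61, 0.62 and 0.50 on the log2 scale. FACT, the fatty alcohol caffeoyl transferase, fell by 0.46, the GDSL lipases GELP38, GELP51 and GELP96, of a family that assembles suberin in the wall, fell by 0.47, 0.51 and 0.59, and the transporters ABCG1, ABCG6 and ABCG20 fell by 0.38, 0.58 and 0.27. The 6 members that did not pass were LTP4 (-2.81, adjusted p = 0.0995), GPAT7, ABCG11, KCS2, ASFT (-0.18) and ABCG16 (0.29), and ABCG2 was too low to test. Camera with the preset correlation gave an adjusted p of 7.71e-12. The call was lost with an estimated correlation (adjusted p = 0.751, unadjusted p = 0.0844), while fry gave an adjusted p of 0.0481. A split of the libraries that mixed the genotypes gave a preset camera p of 1.73e-10, against 3.09e-13 in the real split, both unadjusted. The list stood 0.29, 0.18 and 0.36 above the mean of the 6 libraries in WT 1, 2 and 3 and at -0.34, -0.45 and -0.04 in myb68 myb84 1, 2 and 3. Without myb68 myb84 2 the number lowered was 11. The calls ended for GPAT5 without myb68 myb84 1 or 2 (adjusted p up to 0.0518), for ABCG1 without WT 1, WT 3, myb68 myb84 2 or 3 (0.130), for ABCG6 when any 1 library but myb68 myb84 3 was left out (0.129) and for ABCG20 without any 1 of the 6 (0.166). They also ended for ABCG6 with GC and length offsets (0.0571) and no low-count filter (0.0746), for ABCG20 with limma-voom (0.0504), without organelle genes (0.0516) and in thinned libraries (0.0610), and for ABCG1 in thinned libraries (0.0530). FAR1, FAR4, ABCG1, ABCG11, KCS2 and ASFT overlap annotated neighbours.

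**Figure D2:**
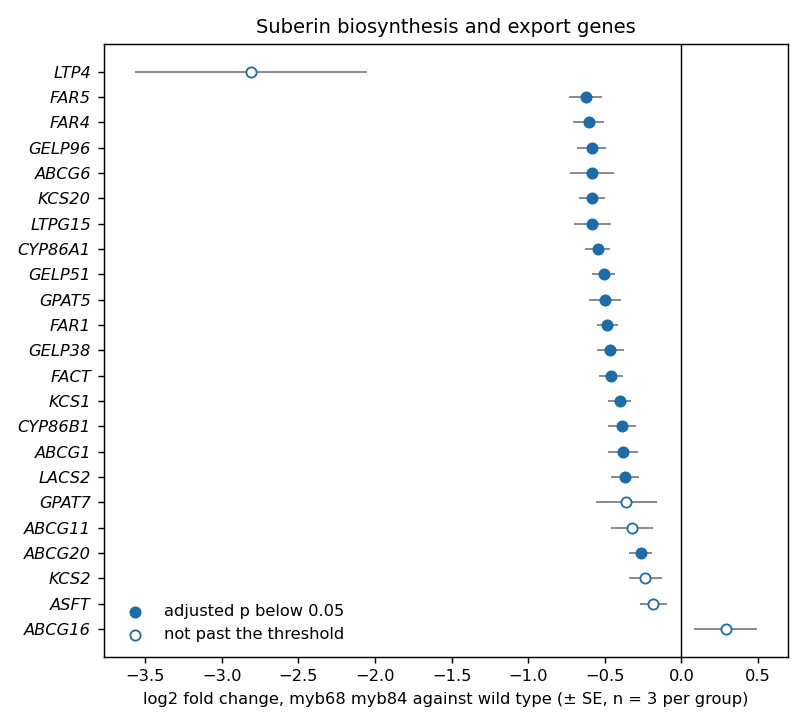
Log2 fold changes of the 23 tested suberin biosynthesis and export genes in myb68 myb84 against wild type (horizontal axis), with bars of 1 standard error and n = 3 libraries per genotype. Filled points mark the 17 genes at an adjusted p under 0.05, all below 0, and open points mark the 6 that did not pass, of which ABCG16 lies above 0.

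The transcription factors known to act on suberin genes did not fall as a group. Of 14 tested, 3 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of 0.07 and a camera adjusted p of 0.889. MYB74, MYB49 and MYB102 rose by 1.03, 0.50 and 1.41, and MYB67 and NAC038 fell by 0.54 and 0.47 on the log2 scale. MYB92, MYB93 and MYB53 did not pass, at 0.19, -0.06 and -0.52. The calls of MYB49, MYB102 and NAC038 each ended without WT 1 (adjusted p = 0.0747, 0.135 and 0.0507), that of MYB49 also without WT 2 or myb68 myb84 3 (up to 0.0830), and that of MYB102 when any 1 library but myb68 myb84 1 was left out (up to 0.178) and in thinned libraries (0.0629). The number raised was 1 without WT 1, WT 2 or myb68 myb84 3, and the number lowered was 1 without WT 1 and 3 without myb68 myb84 3. MYB53 and MYB92 overlap annotated neighbours.

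Genes of cutin and cuticular wax, the lipids of the shoot epidermis that share enzymes with suberin, were also lower. In the cutin list edgeR called 5 of 11 tested members lowered and 0 raised (7 and 0 adjusted over the list alone), with a median of -0.48. Among cutin genes 8, and among wax genes 7, were lower at an unadjusted p under 0.05 and 0 higher, and DESeq2 and limma-voom each called 5 and 4 lowered and 0 raised. GPAT6, an acyltransferase of cutin, went from 26.9 ± 2.62 to 18.0 ± 2.36 CPM and fell by 0.57 on the log2 scale, and CYP86A2, CYP86A4, ABCG32 and GPAT4 fell by 0.48, 0.77, 0.60 and 0.39. In the wax list 4 of 7 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.83. CER6, an elongase of wax precursors, went from 20.6 ± 2.59 to 7.10 ± 2.28 CPM, and CER1, CER5 and LTPG1 fell by 1.96, 0.49 and 0.51 on the log2 scale. Camera gave adjusted p = 0.000158 for cutin and 1.55e-05 for wax, both lost with an estimated correlation (adjusted p = 0.751 for each), and with fry cutin was lost (0.0672) and wax passed (0.0481). By library the cutin list overlapped between genotypes: WT 2 stood at -0.12 against 0.32 and 0.28 in WT 1 and 3, and myb68 myb84 1, 2 and 3 at -0.17, -0.22 and -0.10. The wax list stood at 0.59, 0.46 and 0.51 in WT 1, 2 and 3 and at -0.78, -0.66 and -0.11 in the mutant libraries. The numbers lowered were 2 for cutin and 1 for wax without myb68 myb84 2, 2 for cutin without myb68 myb84 1, 3 for cutin without WT 1 or without myb68 myb84 3, and 2 for wax without WT 1 or without WT 3. Calls ended for CYP86A4 without any 1 mutant library (adjusted p up to 0.0544), ABCG32 without WT 1 or any 1 mutant library (0.138), GPAT4 and CER5 without WT 1, WT 3, myb68 myb84 1 or 2 (0.118 and 0.102), CER1 without any 1 wild-type library or myb68 myb84 2 (0.125) and LTPG1 without myb68 myb84 2 (0.0515). The CER1 call also ended with no low-count filter (0.0908) and the ABCG32 call in thinned libraries (0.0959). CYP86A2 and LTPG1 overlap annotated neighbours.

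Phenylpropanoid and lignin enzymes showed no common direction. Of 22 tested, PAL4 and CCR2 fell by 0.53 and 0.39 on the log2 scale, CAD5 rose by 0.33 and 19 did not pass (1 up and 3 down adjusted over the list alone), with a median of -0.07 and a camera adjusted p of 0.301. The CCR2 call ended without WT 2, WT 3, myb68 myb84 1 or 2 (adjusted p up to 0.0948) and the CAD5 call without WT 1 or myb68 myb84 3 (0.0818). CCR2 overlaps an annotated neighbour.

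Cell cycle genes leaned slightly lower, and few passed singly. Of 40 tested members, 35 had a negative log2 fold change, with a median of -0.18 (-0.11 without myb68 myb84 2), and edgeR called 4 lowered and 0 raised, both over all genes and adjusted over the list alone. At an unadjusted p under 0.05, 9 were lower and 0 higher, and DESeq2 and limma-voom called 5 and 4 lowered and 0 raised. These were the histone H3 genes HTR1 (-0.47), HTR13 (-0.59) and HTR2 (-0.34) and the replication clamp gene PCNA2 (-0.39). The HTR genes encode the same H3.1 protein from near-identical copies, so their reads are hard to assign. Mitotic genes did not pass, as for CYCB1-1 (-0.47, adjusted p = 0.170), KNOLLE (-0.06) and CDKB2-1 (0.03). Camera gave an adjusted p of 0.000158, which was lost with an estimated correlation (adjusted p = 0.751) and with fry (adjusted p = 0.199). By library the genotypes overlapped in this list, with WT 1, 2 and 3 at 0.13, -0.015 and 0.17 and myb68 myb84 1, 2 and 3 at 0.0016, -0.16 and -0.12. Without WT 3, myb68 myb84 2 or myb68 myb84 3 1 gene fell, as in thinned libraries, and without WT 1 or myb68 myb84 1 there were 2. The HTR13 call stayed without WT 1, that of PCNA2 without myb68 myb84 1 and that of HTR2 without WT 2, and each ended in the other 5 such fits (adjusted p up to 0.108, 0.138 and 0.184). In thinned libraries these calls ended too (0.0713, 0.0635 and 0.0632), and that of HTR2 ended with GC and length offsets (0.0737) and without organelle genes (0.0501). PCNA2, KNOLLE and CDKB2-1 overlap annotated neighbours.

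Regulators of the vascular cambium and of stem cells showed no common direction as a group. Fry for changes in either direction gave an unadjusted p of 0.00649 for this list. Of 22 tested members edgeR called 1 raised and 0 lowered, both over all genes and adjusted over the list alone, as did DESeq2 and limma-voom over all genes, with a median of 0.03 and a camera adjusted p of 0.842. KNAT1, a class I KNOX homeobox gene, went from 31.1 ± 3.54 to 44.5 ± 2.51 CPM (log2 0.51, SE 0.09, adjusted p = 0.00344), a call that stayed in all 6 fits with a library left out. WOX4, WOX14 and PXY, central to cambium activity, were at 0.05, 0.02 and 0.10 (adjusted p = 0.877, 0.940 and 0.486). CYCD3-1, which overlaps an annotated neighbour, was at -0.24 and ANT at -0.25 (adjusted p = 0.124 and 0.242). There were 3 higher and 2 lower at an unadjusted p under 0.05, and without WT 3 there were 1 raised and 1 lowered call.

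Endodermal and xylem markers in the segment showed no common direction. The endodermal list had 4 calls among 15 tested genes and the xylem list 2 among 28, against 8.30% of all tested genes. Of 15 endodermal and Casparian strip genes, MYB36 and the GRAS factor gene SCR (0.44) rose and EDA4 (-0.40) and SGN1 (-0.27) fell (2 and 2 adjusted over the list alone, median -0.12, camera adjusted p = 0.697). The CASP genes were among the 11 that did not pass. Of 28 xylem and secondary wall genes, PARVUS rose by 0.45 and GUX2 fell by 0.78 on the log2 scale (1 and 1 adjusted over the list alone), with a median of 0.03 and a camera adjusted p of 0.603. The call of SCR ended without myb68 myb84 1 (adjusted p = 0.0508), that of GUX2 without WT 1 or myb68 myb84 1 (0.0584), that of EDA4 without WT 1, WT 2, myb68 myb84 1 or 2 (0.132), and those of SGN1 and PARVUS when any 1 library but WT 3 was left out (0.202 and 0.136). The EDA4 call also ended with GC and length offsets (0.0545) and in thinned libraries (0.0542). Without WT 2 there were 2 lowered xylem genes. EDA4 overlaps an annotated neighbour.

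Phloem, root tip and reference genes gave 0 calls in edgeR, over all genes or adjusted over the list alone. Of 18 phloem genes (median 0.01, camera adjusted p = 0.792), BAM3 was at -0.01 and PP2-A1, which overlaps an annotated neighbour, at -0.31 (adjusted p = 0.0538). Of the phloem genes 1 was lower at an unadjusted p under 0.05, DESeq2 called 1 lowered and limma-voom 0, and 1 was called lowered without WT 1, with upper-quartile scaling, with no low-count filter, with GC and length offsets and in thinned libraries. The 6 genes of the root tip and root cap had a median of -0.14 (-0.044 without WT 2, -0.047 without myb68 myb84 3, camera adjusted p = 0.464), with 1 lower at an unadjusted p under 0.05 and 0 calls in DESeq2 and limma-voom, while fry passed for this list (adjusted p = 0.0481). The 6 reference genes had a median of -0.01 and a mean of 0.0026, with camera pointing up (adjusted p = 0.989), 0 genes at an unadjusted p under 0.05 and 0 calls in DESeq2 and limma-voom. YLS8, of the reference list, was at 0.05.

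Most genes of photosynthesis were higher in myb68 myb84. By log2 fold change, 24 of 26 tested members lay above 0, within a range from -2.45 to 1.17. Of 26 tested members edgeR called 7 raised and 0 lowered (15 and 1 adjusted over the list alone), with a median of 0.50. LHCB1-2 and LHCB2-1, light-harvesting proteins of photosystem II, rose by 1.17 each, RCA, the Rubisco activase, rose by 0.97 and RBCS1A, a Rubisco small subunit, went from 413 ± 94.7 to 665 ± 37.9 CPM. At an unadjusted p under 0.05, 18 were higher and 1 lower, DESeq2 called 16 raised and 1 lowered, and limma-voom 7 and 0. Camera gave an adjusted p of 1.90e-07, lost with an estimated correlation (adjusted p = 0.797) and with fry (0.220). WT 3 stood apart in this list, at -0.77 from the mean of the 6 libraries against 0.04 and 0.03 in WT 1 and 2 and 0.20, 0.32 and 0.18 in the mutant libraries. Without WT 3 the median was 0.31, with 11 raised and 1 lowered, and 3 and 4 were raised without myb68 myb84 2 and 3. The RCA call ended without myb68 myb84 1 or 2 (adjusted p up to 0.0736) and the RBCS1A call without any 1 mutant library (0.0886). LHCB1-2 has near-identical tandem copies whose reads cannot be told apart with certainty, and RCA overlaps an annotated neighbour.

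Root hair genes were higher as well. Of 10 tested, edgeR called 4 raised and 0 lowered (5 and 0 adjusted over the list alone), with a median of 0.42. LRL3, EXPA7, EXPA18 and COBL9, which act in root hair growth, rose by 0.53, 0.52, 0.48 and 0.37. At an unadjusted p under 0.05, 6 were higher and 0 lower, and DESeq2 and limma-voom called 5 and 4 raised and 0 lowered. Camera gave an adjusted p of 0.000832, lost with an estimated correlation (adjusted p = 0.751) and with fry (0.145). WT 3 was again the lowest library, at -0.45 against -0.08 and -0.13. The number raised was 1 without WT 1 or myb68 myb84 1 and 2 without myb68 myb84 2 or 3. The COBL9 call ended in all 6 such fits (adjusted p up to 0.154) and with upper-quartile scaling (0.0623), the EXPA7 call without WT 1, myb68 myb84 1 or 2 (0.0815) and the EXPA18 call without WT 1 or any 1 mutant library (0.115). EXPA7 and EXPA18 overlap annotated neighbours.

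**Figure D3:**
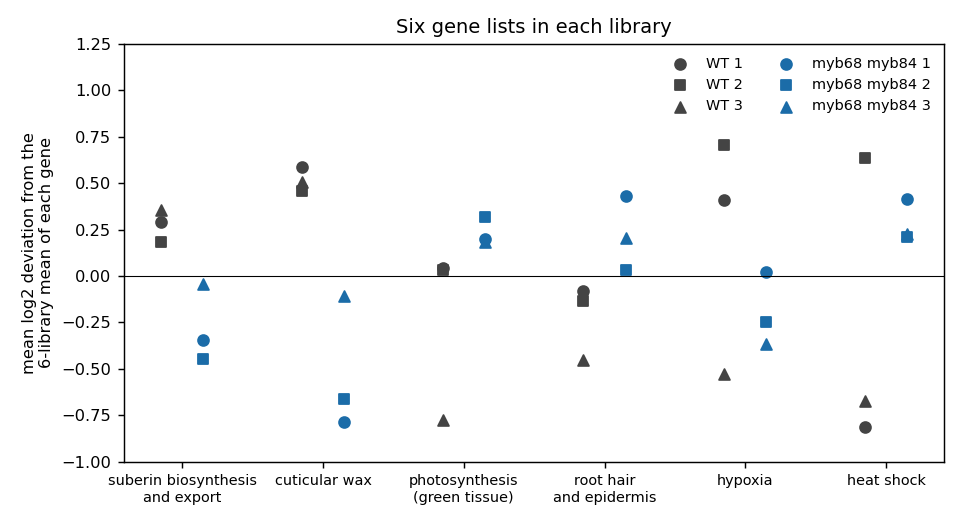
Mean log2 deviation of 6 gene lists from the 6-library mean of each gene (vertical axis), for each library (grey, wild type; blue, myb68 myb84; symbols mark replicates 1 to 3). Suberin and wax genes lie above 0 in the wild-type libraries and below 0 in the mutant ones, WT 3 lies at -0.77 for photosynthesis, and WT 2 lies apart from WT 1 and WT 3 for heat shock.

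Hypoxia genes leaned lower, but the genotypes overlapped by library, with a wide spread among the wild-type libraries. HRA1 fell by 1.14 on the log2 scale, from 14.7 ± 1.44 to 6.68 ± 0.46 CPM, and LBD41 fell by 0.77, while 11 of 13 did not pass (3 lowered and 0 raised adjusted over the list alone, median -0.54, or -0.34 without WT 2). Camera gave an adjusted p of 0.00919, lost with an estimated correlation (adjusted p = 0.806), with fry (0.404), without WT 1 (0.0697) and without WT 2 (0.221). WT 1 and 2 stood at 0.41 and 0.71 and WT 3 at -0.53. The mutant libraries 1, 2 and 3 stood at 0.02, -0.25 and -0.36, so WT 3 lay below each of them. Without WT 3 there were 9 lowered genes, DESeq2 called 4, and there was 1 without WT 1, WT 2, myb68 myb84 1 or 3. The LBD41 call ended when any 1 library but WT 3 was left out (adjusted p up to 0.0953) and with no low-count filter (0.0550).

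Heat shock genes varied as widely. HSP101 and HSP90-1, chaperone genes, rose by 0.96 and 1.22, and 7 of 9 did not pass (4 up and 1 down adjusted over the list alone, median 0.96, camera adjusted p = 0.103). The median was 0.54 without WT 1 and 0.53 without WT 3. WT 2 stood at 0.64 in this list against -0.82 and -0.67 in WT 1 and 3. There were 3 raised and 2 lowered genes without WT 1, 3 and 1 without WT 2, and 1 raised without WT 3 or any 1 mutant library, while DESeq2 called 4 raised and 2 lowered. The HSP90-1 call ended when any 1 library but WT 1 was left out (adjusted p up to 0.110), with GC and length offsets (0.0563), with no low-count filter (0.0858) and in thinned libraries (0.0524). HSP101 overlaps an annotated neighbour.

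Hormone response lists had no camera call. In the abscisic acid list of 22, RD26, ABF3, HAB1 and COR47 rose by 0.74, 0.41, 0.31 and 0.34 and RD22 fell by 1.41 on the log2 scale (4 and 2 adjusted over the list alone, median 0.15, camera adjusted p = 0.464). The number raised was 1 without WT 1 or myb68 myb84 3 and 2 without myb68 myb84 1. Calls ended for ABF3, which overlaps an annotated neighbour, without WT 1 or myb68 myb84 3 (adjusted p up to 0.0661), for HAB1 without WT 1, myb68 myb84 1 or 3 (0.104) and for COR47 when any 1 library but WT 2 was left out (0.177) and with upper-quartile scaling (0.0600). In the jasmonate list of 14, the storage protein gene VSP1 went from 394 ± 74.0 to 171 ± 24.7 CPM and JAZ9 fell by 0.39 (1 up and 3 down adjusted over the list alone, median -0.13, camera adjusted p = 0.301). The JAZ9 call ended without WT 2 (log2 -0.25) or any 1 mutant library (adjusted p up to 0.143), and 1 gene was raised without WT 2. The list median was -0.05 without WT 2 and 0.01 without WT 3. Of the 16 members, MYC2, the main transcription factor of the pathway, and PDF1.2 had 0 counts in all 6 libraries and were not tested, and whether this comes from the counting is not given in the sources used here.

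ARR7, a cytokinin-induced response regulator, fell by 0.75 on the log2 scale as the single call of 12 in its list (0 up and 1 down adjusted over the list alone, median -0.07, camera adjusted p = 0.359), and the call ended without myb68 myb84 2 (adjusted p = 0.0533). Auxin response genes gave 0 calls of 19 in edgeR by either adjustment (median -0.09, camera adjusted p = 0.411), with IAA2 at 0.08. Of the auxin genes 4 were lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0, against 1 lowered in thinned libraries. In the salicylate and defence list of 16, FMO1 fell by 0.78 on the log2 scale (0 up and 2 down adjusted over the list alone, median -0.05, camera adjusted p = 0.650). The FMO1 call ended when any 1 library but WT 2 was left out (adjusted p up to 0.125) and in thinned libraries (0.261), while 3 were lowered without WT 2, 1 was raised without WT 3 and DESeq2 called 2 lowered.

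Nutrient and specialised metabolism lists had no camera call. The phosphate list had 3 calls among 12 tested genes and the iron list 2 among 17, against 8.30% of all tested genes. For phosphate starvation, PHO1-H1 and PAP17 rose by 0.80 and 0.71 and the ribonuclease gene RNS1 fell by 1.14 on the log2 scale among 12 (3 and 1 adjusted over the list alone, median 0.16, camera adjusted p = 0.298). For iron deficiency, NAS4 rose by 0.91 and F6H1 fell by 0.32 among 17 (2 and 3 adjusted over the list alone, median 0.08, camera adjusted p = 0.667), and 4 were raised without WT 3. The PHO1-H1 call ended without WT 2 or any 1 mutant library (adjusted p up to 0.0791), that of PAP17 without WT 1, WT 3 or myb68 myb84 2 (0.0983) and that of F6H1 without WT 1 or any 1 mutant library (0.125). The PAP17 call also ended with no low-count filter (0.0589) and the F6H1 call in thinned libraries (0.0551). The root triterpene clusters gave 0 calls of 9 in edgeR (1 up and 0 down adjusted over the list alone, median 0.20, camera adjusted p = 0.603), with THAD at -0.13. At an unadjusted p under 0.05, 1 was higher, DESeq2 and limma-voom called 0, and 1 was raised with no low-count filter. PAP17 and F6H1 overlap annotated neighbours.

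**Figure D4:**
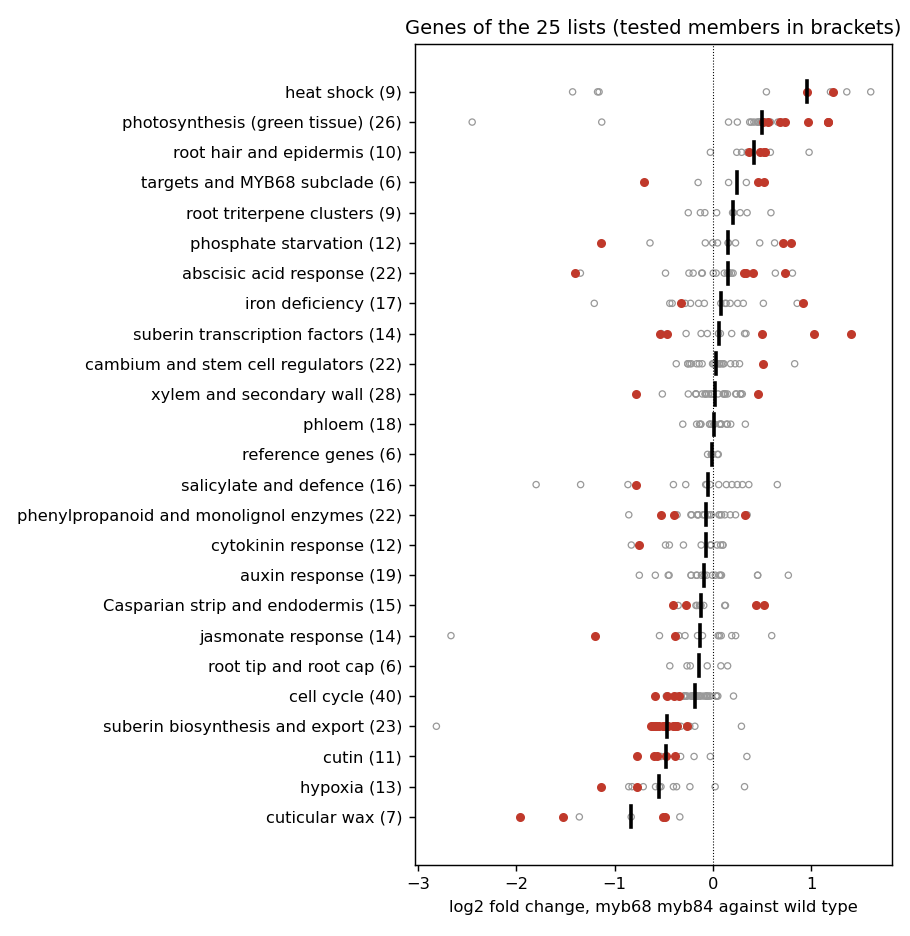
Log2 fold change in myb68 myb84 against wild type (horizontal axis) of each tested gene in the 25 lists, sorted by median (black bars). Red points passed at an adjusted p under 0.05 and open points did not; the medians run from -0.83 for cuticular wax to 0.96 for heat shock, the latter at 0.54 without WT 1 and 0.53 without WT 3.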

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

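Thinned libraries and the lists under other scalings were chosen after seeing the data. The called genes numbered 742 (425 raised, 317 lowered) at an adjusted p under 0.01 and 284 (151, 133) at 2-fold or more, by construction. Without 1 library they numbered 1024 to 1670, raised 579 to 947 and lowered 435 to 723, and 55.1% to 76.9% of the 1739 genes were called again. Other fits gave 1484 (thinned) to 2156 genes. Upper-quartile scaling gave 875 raised and 895 lowered, moving the raised share from 56.1% to 49.4% and the median of all genes to -0.02. The replicate numbers did not pair the samples: same-number deviations correlated at -0.01, 0.02 and 0.08, 2 of the 6 libraries matched best with their own number, and the replicate block gave 2069 genes (1154, 915), or 2156 with GC and length offsets. Of 119 called genes followed by name, 70 stayed called in all 6 fits with a library left out.

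The suberin and cell cycle lists were lost with an estimated correlation (adjusted p = 0.751 each), and the cell cycle and cutin lists with fry (0.199 and 0.0672); the cause was not tested beyond the larger correlation. The suberin adjusted p otherwise ran from 1.50e-15 to 1.86e-09 without 1 library. Lists that did not pass changed sign: in thinned libraries cambium, suberin factors and reference genes (0.873 each), with upper-quartile scaling (0.858) and fry (0.983) reference genes, and MYB37 when thinned (log2 0.074). The cause was not tested. Lists that changed sign without 1 library had adjusted p from 0.506 to 0.998 (Casparian strip), 0.287 to 0.969 (iron), 0.838 to 0.981 (reference), 0.506 to 0.969 (suberin factors and cambium), 0.475 to 0.967 (phloem), 0.0607 to 0.957 (salicylate), 0.221 to 0.998 (abscisic acid) and 0.15 to 0.662 (triterpene). With the block the SGN1 and HSP90-1 calls ended (0.0511 and 0.167), MYB68 and PRR3 passed (0.00999 and 0.0466), 17 photosynthesis genes and 1 triterpene gene rose and 1 phloem gene fell. With libraries thinned to 19446419 counts, 1484 of 20085 tested genes were called.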

Other observations

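The splits of the libraries were planned, while the clock and aquaporin lists, the counts by product name, the windows around MYB68 and MYB84 and each test of an explanation were chosen after the results were seen.

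Circadian clock genes were higher in myb68 myb84. Of 21 tested members edgeR called 14 raised and 7 did not pass, with a median of 0.41. The list gave a camera p of 9.08e-11, a camera p of 0.00767 with an estimated correlation and a fry p of 1.23e-04, none of them adjusted. These p-values describe a list chosen from the same libraries after PRR9 was seen among the largest rises, so they do not test the rise. CCA1 and LHY, morning-phase MYB factors, went from 17.8 ± 3.73 to 28.8 ± 1.48 CPM and rose by 0.70 and 0.99, and GI, an evening-phase gene, went from 79.4 ± 13.2 to 141 ± 7.44 CPM. RVE7, a relative of CCA1, went from 24.3 ± 2.02 to 62.4 ± 8.92 CPM, and LNK1 rose by 1.41. PRR7 (0.28), PRR5 (0.30) and PRR3 (-0.26) did not pass. PRR3, at an adjusted p of 0.0501, passed as lower with DESeq2 size factors (0.0498), upper-quartile scaling (0.0351), the stricter filter (0.0462), limma-voom (0.0472), GC and length offsets (0.0292) and without WT 2 (0.0305), and its adjusted p over all alternatives ran up to 0.194. The LHY call ended without WT 1, WT 2, myb68 myb84 1 or 3 (adjusted p up to 0.10), and without WT 2 the list had 11 raised and 1 lowered. Among 13 plasma membrane aquaporins 5 rose and 2 fell in edgeR, with a median of 0.09 and a limma camera p of 0.106, and with PIP2C going from 98.5 ± 15.8 to 198 ± 22.0 CPM. The number of aquaporins raised was 3 without WT 1. Their median was 0.13 without WT 1, 0.04 without WT 3 and 0.05 without myb68 myb84 3. The calls of PIP1C and PIP2-8, which fell by 0.32 and 0.44 on the log2 scale, ended when any 1 library but WT 3 was left out, with adjusted p up to 0.173 for PIP1C.

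Product names of the called genes were counted over 1706 terms, each with 10 to 300 tested genes, by one-sided hypergeometric tests that treat genes as independent, and 100 of 3412 tests passed after Benjamini-Hochberg adjustment, which held 72 distinct sets of genes and directions because several terms name the same genes. Disease resistance genes had 27 raised of 141 against 6.56 expected (adjusted p = 7.51e-07) and 4 lowered. RPP4, an immune receptor gene, went from 14.2 ± 1.28 to 28.3 ± 2.45 CPM, and SNC1 and ADR1 rose by 0.53 and 0.70, with RPP4 and SNC1 in a cluster of similar copies whose reads cannot be told apart with certainty. Chlorophyll terms had 9 raised of 18 (adjusted p = 8.36e-06) and B-box factors 8 of 19 (1.30e-04), among them STO, which went from 61.9 ± 10.99 to 121 ± 7.03 CPM. Among lowered genes were 12 of 44 lipid-transfer proteins (8.36e-06), 12 of 49 GDSL-like lipases (2.21e-05), 12 of 56 of the peroxidase superfamily (9.26e-05) and 6 of 10 of an O-methyltransferase family (6.36e-05). The peroxidase gene AT2G38390 went from 393 ± 27.5 to 146 ± 13.3 CPM and the O-methyltransferase gene AT1G77520 from 100.3 ± 23.1 to 29.4 ± 3.80 CPM. Without 1 library the counts were 5 for B-box factors (myb68 myb84 1 or 3), 5 for lipid-transfer proteins (WT 1 or myb68 myb84 2) and 7 (myb68 myb84 1), and 7 for GDSL-like lipases (WT 1 or myb68 myb84 1). Within 1 Mb of MYB68, 38 of 428 genes were called (8.88% against 8.32% elsewhere, Fisher's exact two-sided p = 0.659), among them AT5G65400, one of the genes lowered at least 16-fold, at a distance of 0.19 Mb, and within 1 Mb of MYB84, 31 of 454 (6.83% against 8.37%, p = 0.265).

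The tested genes of the chromosome 1 interval from 3220035 to 3241863 held at most 1.14% of their wild-type level in myb68 myb84, while the neighbours stood at 109% and 102%. Random placement of the genes lowered at least 16-fold gave no run as long in 10000 draws (permutation p = 1e-04, the smallest they can give), which argues against single losses lying together by chance. A segment absent from the mutant line, or unlike the reference there, may account for the pattern. Regulation by MYB68 and MYB84 stays open, because the samples hold 1 mutant genotype, and a second line or genomic DNA of this one would test it.

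Suberin and wax genes were lower in each mutant library than in each wild-type library by list mean, while for cutin WT 2 (-0.12) lay below myb68 myb84 3 (-0.10). GC content and length bias are argued against by a suberin median of -0.46 with offsets for both, with 16 genes lowered, and the shallow WT 3 by a median of -0.50 without it. The suberin genes fell by unequal amounts, which a common factor would not give. Cochran Q against a chi-square distribution with 22 degrees of freedom gave p = 3.45e-05, with genes taken as independent. A smaller share of suberised tissue in the mutant segments may still contribute. It stays open because suberin genes may differ in how far other tissues express them, and no member rose, while root hair (median 0.42) and photosynthesis genes (0.50) were higher and xylem (0.03) and phloem genes (0.01) were near 0. An effect of the genotype on expression per cell stays open, not tested apart from tissue share. The line also differed in the chromosome 1 interval and at other genes. AT1G27565 had 725 counts in wild type and 0 in the mutant, and AT1G75945 had 4 and 1151. With 1 mutant genotype, changes in any list cannot be assigned to MYB68 and MYB84 apart from such differences.

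The rise of clock genes did not rest on WT 3, since the median was 0.45 without it. Green shoot tissue carried into the mutant segments could raise light-regulated genes. Cutin and wax genes, of the shoot epidermis, were lower in the mutant (medians -0.48 and -0.83), which carried shoot tissue alone would not give. Without WT 3 the photosynthesis median minus the clock median was -0.14 (one-sided permutation p = 0.0659). Over all 6 libraries the photosynthesis median minus the clock median was 0.092, which leaves a part for green tissue open. A different time of day at collection could also shift these genes, although the labels give continuous light, and 0 libraries have a labelled collection time. An effect of the genotype on the clock stays open as well and was not tested apart from these or from the chromosome 1 losses.

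The 6 libraries split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1739 called genes in edgeR (975 raised, 764 lowered) and the highest other split 0, with up to 971 genes at an unadjusted p under 0.05, against 4615 in the real split, and 0 calls by limma-voom, against 1874. In 1 of the 10 splits, the real one, were the counts as large. Every other split mixed the genotypes within its groups. A genotype effect then adds to the spread within groups, so these splits give few calls and are no null for the counts. Camera p for the suberin list was 3.09e-13 in the real split and 1.73e-10 in the lowest other (1 of 10 as small). For the cell cycle list it was 3.16e-05 against 1.01e-11 (2 of 10), and for the cambium list 0.774 against 0.00953 (9 of 10). Since splits that mixed the genotypes gave p-values this small, camera p-values with the preset correlation cannot be taken at face value.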
